A study of Mus musculus with 10 samples.

How the data were processed

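RNA was measured on Affymetrix arrays in the decidua, the maternal tissue that forms around an implanted embryo, of 10 female mice at embryonic day 7.5. In 5 mice both Notch1 alleles were floxed and Cre stood in for 1 copy of the progesterone receptor gene Pgr (PgrCre/+Notch1f/f, here called knockout). The other 5 had the floxed alleles without Cre (Pgr+/+Notch1f/f, here called control). Of each genotype, 3 mice were in the first and 2 in the fourth pregnancy. Each array came from a separate mouse, and arrays are named by genotype, pregnancy (first, or later for the fourth) and the replicate number of their titles, as in control later 2. Per the labels' protocols, myometrium and embryo were dissected away before RNA extraction, and total RNA was labelled with biotin for hybridisation. Neither scan dates nor batches were given, so a difference in handling between pregnancies cannot be told apart from pregnancy number. The same holds for a difference in the age of the mice.

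The values used were the intensity values deposited by the authors, 1 per probe set and array. GCOS 1.4 was listed per the submitters' processing notes, without its role, and the summary and normalisation methods were not stated. The deposited values were on a linear scale, and their distributions were nearly equal between arrays. A scaled single-array signal had been assumed when the fit was planned; the closely matched quantiles and the lack of values near 0 looked more like the output of a model fitted to all arrays, and the plan for linear values was kept. Control probe sets of the array were not among the values used, so the planned 3'/5' ratios and hybridisation controls could not be computed. No other column held values per sample.

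The table held 45037 probe sets, of which 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none. Entrez numbers matched 34741 of the 34945 to the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. The gene table served for names and for the order of neighbouring genes, and no coordinates are given. An offset of 4.15, the 20th percentile of all signals, was added before taking log2. Of each of 18193 genes the probe set with the highest mean log2 value over the 10 arrays was used, and it was tested if that mean was above the 40th percentile of all probe sets, a signal of 5.99. This left 13025 genes.

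Group means of the 4 groups were fitted in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation (trend and robust). The fit had 6 residual degrees of freedom, and the median prior added 3.61. There were 6 comparisons: knockout against control in the first pregnancy, in the fourth pregnancy and as the mean of both, the difference between the knockout effects of both pregnancies, and the fourth against the first pregnancy within each genotype. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the 13025 genes. Log2 fold changes are of signal plus offset and are given with their SE; signals are given as mean and SD. The number of arrays limits the precision.

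The comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except those named in the closing part as chosen later. The rule named the 10 genes with the largest rise and the 10 with the largest fall among genes that passed and whose arrays did not overlap between groups. Where fewer than 5 passed in a direction, it named the 5 of smallest p. Notch1, Pgr and up to 4 members of smallest p of each described list were named too, and genes known only by a clone number were skipped. For genes named by size of change or smallest p, the values of their other probe sets past the filter are given where 1 of these turned the sign or gave a change over 1.5 times smaller. Further members of the lists, such as Hes1 and Prl8a2, were named after their values were seen. There were 45 lists of pathway genes and cell type markers, of which 44 had at least 4 tested members and are named with their results in the report. The other, of Y-linked genes of male embryos, had 1 tested member and was not tested. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 44 lists of a comparison, and again with an estimated correlation.

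Correlations between effects, Notch1 and Pgr were also tested by exact two-sided permutation of the genotype labels within pregnancy. The gene test was tested on simulated data with the spread of these 13025 genes. In the first-pregnancy comparison it recovered 76.1%, 94.0% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale, and 6.25% of its calls were false. In the fourth-pregnancy comparison it recovered 65.7%, 86.6% and 97.0%, with 4.05% of calls false. In the mean effect it recovered 85.1%, 97.0% and 100%, with 4.08% of calls false. The noise of these gene simulations was normal and independent between genes and arrays, and no simulated array stood apart. Recovery and false calls in the real arrays may therefore differ. In the first-pregnancy simulation lists were called at an unadjusted p under 0.05, unlike the adjusted calls of the results. At its preset correlation camera called 2.5% of 40 unchanged lists of independent genes. It called 36% of 50 unchanged lists whose genes were correlated at 0.2. With an estimated correlation it called 10% of those 50.

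The alternatives were no offset, 4 times the offset, quantile normalisation, no filter, a stricter filter at the 60th percentile, every probe set in place of 1 per gene, moderation without trend and robust settings, a fit on only the arrays of a comparison, a replicate block, the other probe sets of Notch1 and Pgr, an estimated correlation for camera, and leaving out each array in turn. Leaving out both arrays that stand apart, and the left-out values of lists, were added after the data were seen. Leaving out an array of the fourth pregnancy leaves its group with 1 array, which is then assumed to vary like the other groups. Probe sets without exactly 1 symbol were left out of the gene test, and the closing part gives their count.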

Results

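The series asked how loss of Notch1, a receptor for signals between neighbouring cells, in the uterus alters gene expression of the decidua in a first and a later pregnancy. There were 3 knockout and 3 control arrays from the first pregnancy, and 2 knockout and 2 control arrays from the fourth pregnancy. The median signal per array lay between 8.14 and 8.36, and the sum of signal between 4373240 and 4457050. Pearson r of log2 signal was 0.988 to 0.996 between arrays of a group and 0.977 to 0.996 between any pair. The first principal component held 42.2% and the second 20.2% of the variance. Array knockout first 1 lay farthest from 0 on the first component, at -24.5, and control first 5 on the second, at 20.3. Both are called the arrays that stand apart below, for this position alone. Control later 2 lay at 21.1 on the first component. The mean r of knockout first 1 with its own group was 0.994, above that of every control array (0.989 to 0.993).

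Signal of Notch1, the targeted gene, was not lower in the knockout mice. It measured 73.9 ± 9.34 in control and 80.1 ± 3.05 in knockout arrays of the first pregnancy (SD, n = 3 each), and 72.5 ± 9.90 and 79.5 ± 3.03 in the fourth (SD, n = 2 each). The mean log2 fold change was 0.12 ± 0.08 (adjusted p = 0.458; exact permutation p = 0.2), with a 95% interval from -0.05 to 0.30, which excludes a fall below a ratio of 0.964 in what this probe set binds. A second probe set of Notch1 gave 0.04 (exact permutation p = 0.267). The labels do not say which exons are deleted, so it is not known whether the probe sets lie in the deleted part. Pgr, whose locus carries Cre in the knockout mice, gave a mean log2 fold change of 0.05 ± 0.05 (adjusted p = 0.669; exact permutation p = 0.367). Its signals were 934 ± 42.8 and 971 ± 26.0 in control and knockout arrays of the first pregnancy and 924 ± 88.0 and 953 ± 69.6 in those of the fourth. Its other probe sets, both dimmer, gave 0.13 (exact permutation p = 0.117) and, in the opposite direction, -0.17 (exact permutation p = 0.0333, where 0.0167 is the smallest possible). The latter had signals of 10.4 ± 1.13 in control and 8.98 ± 0.823 in knockout arrays of the first pregnancy and 11.4 ± 1.02 and 9.35 ± 0.452 in the fourth. Adjusted over the 5 probe sets of Notch1 and Pgr, its exact permutation p was 0.167, the lowest of the 5. The direction for Pgr thus differed between its probe sets. Of 19 tested Notch target genes, Il2ra rose in the mean of both pregnancies (0.33 ± 0.05), and Id3 (-0.62 ± 0.11) and Efnb2 (-0.50 ± 0.11) fell, and 16 did not pass; adjusted over the list alone, 2 rose and 2 fell (camera adjusted p = 0.408). The values of Hes1 (-0.08), Hey1 (0.03), Heyl (0.07) and Nrarp (0.05), direct targets of Notch receptors in many tissues, did not pass.

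**Figure D1:**
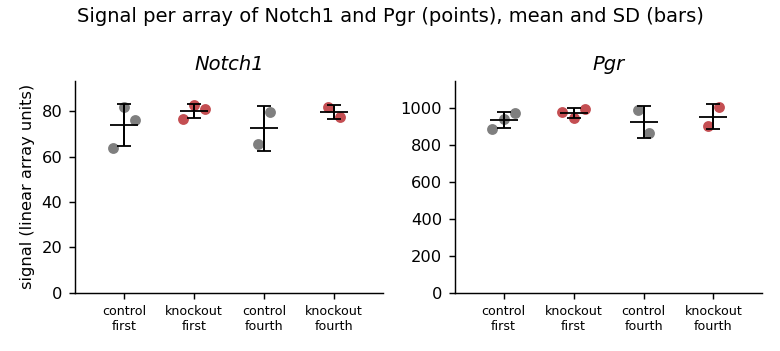
Signal of Notch1 (left) and Pgr (right) per array, in linear array units, in both groups of the first (n = 3 each) and the fourth (n = 2 each) pregnancy. Points are arrays and bars are the group mean and SD. Knockout and control arrays overlap for both genes in the probe sets shown, with mean log2 fold changes of 0.12 and 0.05.

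In the first pregnancy, knockout decidua differed from control decidua in 412 of 13025 genes. Lyve1, a hyaluronan receptor of lymphatic endothelium and some macrophages, rose from 38.6 ± 24.3 to 222 ± 81.4 (SD, n = 3 each), a log2 fold change of 2.50 ± 0.39. Fras1, a matrix protein of basement membranes, fell from 56.8 ± 21.5 to 12.6 ± 2.44 (-1.81 ± 0.28). Of the 412 genes, 193 rose and 219 fell, and 54 changed over 2-fold. Which direction held more genes varied with the arrays used: 275 rose and 149 fell without knockout first 1 and control first 5 together, 76 and 39 without knockout first 1 and 447 and 358 without control first 5. At an unadjusted p under 0.05 there were 2262 genes, where 651 would be expected by chance.

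Adh1, an alcohol dehydrogenase that oxidises retinol and ethanol, rose from 88.7 ± 17.8 to 332 ± 182 (1.74 ± 0.34). Bco1, which cleaves beta-carotene to retinal, rose from 198 ± 88.6 to 671 ± 152 (1.80 ± 0.31). Il1r2, a decoy receptor for interleukin-1, rose from 316 ± 197 to 1099 ± 209 (1.94 ± 0.36). Pdzk1ip1, a small membrane protein, rose from 230.5 ± 67.0 to 906 ± 74.2 (2.00 ± 0.24), and the placental prolactin-family hormone Prl7a1 from 8.53 ± 3.60 to 49.7 ± 16.1 (2.08 ± 0.29). Ccdc141 had the smallest adjusted p, 0.000127, at 1.88 ± 0.10. Vwce (1.99 ± 0.28), the cytochrome P450 gene Cyp2b10 (1.69 ± 0.17) and Fam210b (1.68 ± 0.23) rose too. Among the falls, the integrin subunit Itga8 went from 177 ± 16.3 to 63.6 ± 12.8 (-1.43 ± 0.18) and the matrix protein Coch from 1409 ± 330.4 to 524 ± 78.1 (-1.4 ± 0.23). Alkaline phosphatase, Alpl, a long-used marker of decidual stroma, fell from 138 ± 37.9 to 60.2 ± 6.83 (-1.12 ± 0.17). Spon2, a secreted matrix protein (-1.33 ± 0.20), the adenylate kinase Ak1 (-1.24 ± 0.17) and the ectonucleotidase Enpp3 (-1.27 ± 0.21) fell. The kinase Rps6ka6 (-1.38 ± 0.27), C1qtnf2 (-1.23 ± 0.16) and Pamr1 (-1.13 ± 0.18) fell too. Other probe sets gave smaller changes for several of these genes: -0.32 for Fras1, -0.41 for Itga8, -0.58 for Rps6ka6 and -0.02 for Spon2. The 3 others of Enpp3 gave -0.01, -0.62 and -1.79, those of Ccdc141 0.02, 0.60 and 1.76, and both others of Cyp2b10 0.98 and 1.4.

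Several lists of cell type markers and pathway genes were shifted in the first pregnancy at camera's preset correlation, and 0 of 44 with an estimated one. Of 19 tested markers of uterine natural killer cells, 0 rose, 0 fell and 19 did not pass; adjusted over the list alone, 7 rose and 0 fell. Their median log2 fold change was 0.77, and the list was shifted upward against other genes (camera adjusted p = 4.44e-08; adjusted p = 0.677 with an estimated correlation). The smallest p were those of Fcer1g (0.72 ± 0.18), Klra7 (0.52 ± 0.15), Tyrobp (0.72 ± 0.20) and the granzyme Gzmf (1.28 ± 0.38). Of these, Fcer1g and Tyrobp are not particular to natural killer cells among leukocytes. An upward shift held too for 28 interferon-stimulated genes, with a median of 0.36, of which 0 rose, 0 fell and 28 did not pass. With interferon-stimulated genes adjusted over the list alone, 11 rose and 0 fell (camera adjusted p = 2e-07; adjusted p = 0.677 with an estimated correlation). Dhx58 (0.46 ± 0.11), Ifit1 (1.05 ± 0.25), Ifit3 (0.50 ± 0.13) and Oasl2 (0.67 ± 0.18) led it. Class I antigen presentation, with 12 members, had a median of 0.25, and 0 rose, 0 fell and 12 did not pass. With class I genes adjusted over the list alone, 4 rose and 0 fell (camera adjusted p = 0.000123; adjusted p = 0.677 with an estimated correlation). The proteasome subunits Psmb8 (0.33 ± 0.08) and Psmb9 (0.29 ± 0.09) and the peptide transport genes Tap1 (0.23 ± 0.07) and Tapbp (0.37 ± 0.12) had its smallest p.

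Trophoblast markers, of which Prl7a1 and Plac1 (0.82 ± 0.18) passed, had 12 tested members with a median of 0.26: 2 rose, 0 fell and 10 did not pass, and adjusted over the list alone 6 rose and 0 fell (camera adjusted p = 0.00178; adjusted p = 0.677 with an estimated correlation). Ceacam9 (0.35 ± 0.09) and Prl4a1 (1.28 ± 0.40) followed. Among 24 endothelial markers, Lyve1 alone rose and 0 fell, and adjusted over the list alone 2 rose and 0 fell. The endothelial median was 0.09 (camera adjusted p = 0.0234; adjusted p = 0.737 with an estimated correlation). Cdh5 (0.53 ± 0.13), Emcn (0.55 ± 0.18) and Icam2 (0.38 ± 0.13) came next. In the unfolded protein response list of 23 genes, Xbp1 (0.22 ± 0.05), a transcription factor of that response, rose, 0 fell and 22 did not pass, and adjusted over the list alone 1 rose and 0 fell. The median of this list was 0.10 (camera adjusted p = 0.000224; adjusted p = 0.677 with an estimated correlation). Herpud1 (0.54 ± 0.17), Sdf2l1 (0.25 ± 0.09) and Asns (0.33 ± 0.13) did not pass.

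Lists shifted downward were mitosis, DNA replication, and BMP and Wnt signalling. Mitosis genes, 26 in number, had a median of -0.27; 0 rose, 0 fell and 26 did not pass, and adjusted over the list alone 0 rose and 0 fell (camera adjusted p = 4.59e-06; adjusted p = 0.703 with an estimated correlation). Cdc20 (-0.42 ± 0.13), Kif20a (-0.48 ± 0.16), Bub1 (-0.38 ± 0.13) and Aurka (-0.36 ± 0.13) had the smallest p. The 28 DNA replication genes had a median of -0.18; 0 rose, 0 fell and 28 did not pass, and adjusted over the list alone 0 rose and 0 fell (camera adjusted p = 0.00499; adjusted p = 0.737 with an estimated correlation). Rrm1 (-0.23 ± 0.08), Mcm3 (-0.23 ± 0.09), Pcna (-0.16 ± 0.06) and Mcm4 (-0.32 ± 0.14) led it. In BMP and Wnt signalling, the Wnt receptor Fzd7 (-0.71 ± 0.09), the Wnt inhibitor Sfrp5 (-0.86 ± 0.14), the ligand Wnt4 (-0.38 ± 0.09) and the BMP effector Smad5 (-0.29 ± 0.07) fell. That list had 30 members, of which 0 rose, 4 fell and 26 did not pass. With these 30 adjusted over the list alone, 0 rose and 6 fell, with a median of -0.10 (camera adjusted p = 0.0103; adjusted p = 0.677 with an estimated correlation). The count of 412 became 805 without control first 5, 115 without knockout first 1, 171 without knockout first 2, 106 without knockout first 3, 115 without control first 3, 198 without control first 4 and 258 without either knockout array of the fourth pregnancy. The endothelial call was lost without knockout first 2, knockout first 3 or control first 3 (highest adjusted p = 0.409), and the DNA replication call without knockout first 1, control first 3 or control first 4 (0.182). The BMP and Wnt call was lost without knockout first 1 (0.0505). The mean of the mitosis list, -0.27, was -0.16 without knockout first 1, and its median relative to all arrays was -0.21 in control first 5, against -0.20 in knockout first 3 and -0.08 in knockout first 2. The mean of DNA replication, -0.17, was -0.11 without knockout first 1, -0.09 without control first 4 and -0.28 without control first 5, and that of endothelium, 0.24, was 0.14 without control first 3.

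**Figure D2:**
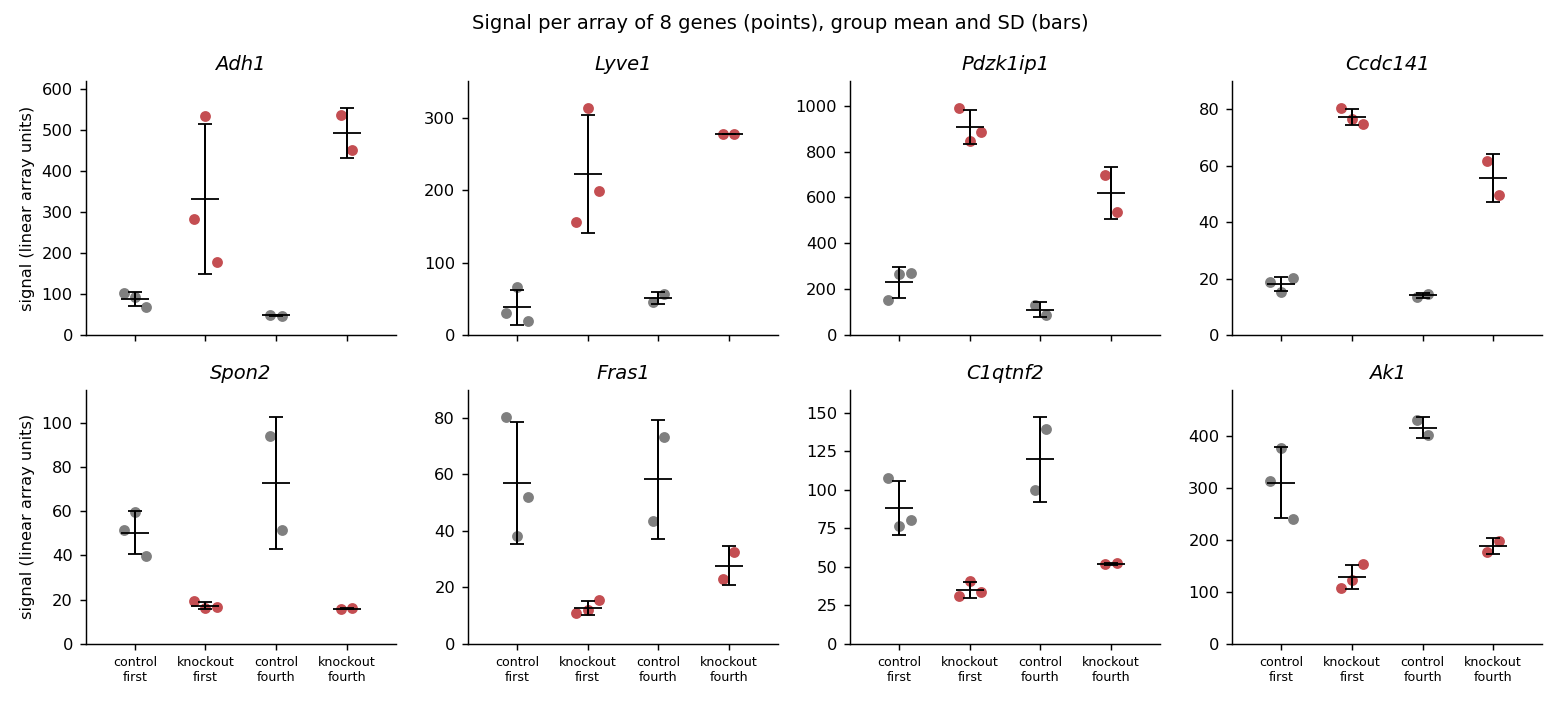
Signal per array of 8 named genes, in linear array units, in the control (grey) and knockout (red) groups of the first (n = 3 each) and the fourth (n = 2 each) pregnancy. Points are arrays and bars are the group mean and SD. For Adh1, Lyve1, Pdzk1ip1 and Ccdc141 every knockout array lies above every control array of its pregnancy, and for Spon2, Fras1, C1qtnf2 and Ak1 below. The naming rule admitted only genes whose arrays do not overlap, so this separation follows from the selection.

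In the fourth pregnancy, 62 genes differed between knockout and control decidua. Adh1 rose from 48.5 ± 0.693 to 493 ± 60.1 (SD, n = 2 each), a log2 fold change of 3.23 ± 0.42. Spink1, a protease inhibitor of secretory epithelia, rose from 7.01 ± 0.508 to 83.3 ± 36.9 (2.90 ± 0.46), and the tight junction gene Cldn3 from 76.2 ± 2.05 to 205 ± 56.5 (1.36 ± 0.19). Spon2 fell from 72.9 ± 29.97 to 15.9 ± 0.353 (-1.88 ± 0.25), although a second probe set gave -0.11. Of the 62 genes 27 rose, 35 fell and 17 changed over 2-fold. In most other settings more genes fell too. In a fit on only the fourth-pregnancy arrays, however, 29 rose and 24 fell, and 25 rose and 20 fell without knockout first 3. At an unadjusted p under 0.05 there were 1455 genes, where 651 would be expected.

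Pdzk1ip1 (2.46 ± 0.29) and Ccdc141 (1.71 ± 0.13) rose as in the first pregnancy. Bmper, which binds bone morphogenetic proteins outside the cell, rose from 11.4 ± 0.275 to 38.4 ± 6.78 (1.44 ± 0.13), and the nucleotide receptor P2ry6 from 17.9 ± 3.04 to 53.0 ± 10.9 (1.37 ± 0.19). The acyl-CoA synthetase Acsbg1 (1.35 ± 0.11), the tetraspanin Tspan8 (1.29 ± 0.18) and the sorting nexin Snx10 (1.11 ± 0.16) rose; a second probe set of Snx10 gave 0.09, the 3 others of Tspan8 gave 0.73, 0.16 and 0.14, and those of Ccdc141 0.55, 0.16 and 1.77. Among falls, the cell cycle inhibitor Cdkn1b went from 132 ± 2.25 to 65.7 ± 3.87 (-0.97 ± 0.10), while a second probe set of Cdkn1b gave 0.03. Pam, an enzyme that amidates peptide hormones, fell from 566 ± 89.9 to 237 ± 8.77 (-1.23 ± 0.20), and Prss35 from 92.7 ± 17.7 to 35.7 ± 4.28 (-1.27 ± 0.16). The sulfatase Arsj (-1.35 ± 0.17), C1qtnf2 (-1.13 ± 0.19) and the glycosyltransferase Galnt18 (-1.05 ± 0.16) fell. The Ras activator Rasgrp1 (-1.04 ± 0.10; second probe set -0.16), the transporter Abca13 (-0.90 ± 0.11) and Tmem35a (-0.82 ± 0.09) fell.

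Among gene lists of the fourth pregnancy, markers of luminal and glandular epithelium were shifted upward. Of 20 members, Spink1 and Cldn3 rose, 0 fell and 18 did not pass, and adjusted over the list alone 6 rose and 1 fell. The epithelial median was 0.34 (camera adjusted p = 0.00928; adjusted p = 0.740 with an estimated correlation). Cdh1 (0.69 ± 0.13) and the gland protease Prss28 (3.08 ± 0.60) did not pass. Natural killer cell markers had a median of 0.46; 0 rose, 0 fell and 19 did not pass, and adjusted over the list alone 0 rose and 0 fell (camera adjusted p = 0.00928; adjusted p = 0.911 with an estimated correlation). Gzma (1.17 ± 0.48) and Gzmg (1.51 ± 0.65) had the smallest p. The unfolded protein response list, with Asns at 0.55 ± 0.15 and Herpud1 at 0.59 ± 0.21, had a median of 0.07, and 0 rose, 0 fell and 23 did not pass; adjusted over the list alone, 0 rose and 0 fell (camera adjusted p = 0.0298; adjusted p = 0.911 with an estimated correlation). The epithelial call was lost without control later 1 (adjusted p = 0.0517), the natural killer call without control later 2 (0.731) or knockout later 2, and the unfolded protein response call without control later 2 (0.157), control later 1 or knockout later 2. The natural killer mean, 0.53, was 0.11 without control later 2, 0.26 without knockout later 2, 0.80 without knockout later 1 and 0.95 without control later 1.

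Complement and coagulation genes were shifted downward in the fourth pregnancy, with a median of -0.08 over 20 members; 0 rose, 0 fell and 20 did not pass, and adjusted over the list alone 0 rose and 5 fell (camera adjusted p = 0.00928; adjusted p = 0.740 with an estimated correlation). The complement protease C1s1 (-0.51 ± 0.10) and the inhibitors Serping1 (-0.45 ± 0.09) and Cd59a (-0.53 ± 0.11) had its smallest p. Cholesterol synthesis had a median of -0.15, with Mvk at -0.30 ± 0.12 and Hmgcs1 at -0.28 ± 0.12; 0 rose, 0 fell and 18 did not pass, and adjusted over the list alone 0 rose and 0 fell (camera adjusted p = 0.0270; adjusted p = 0.911 with an estimated correlation). Matrix remodelling had a median of -0.24, with Sparc at -0.25 ± 0.06, Timp1 at -0.32 ± 0.09 and Eln at 1.42 ± 0.40; 0 rose, 0 fell and 21 did not pass, and adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.0358; adjusted p = 0.911 with an estimated correlation). In BMP and Wnt signalling Fzd7 was at -0.54 ± 0.11 and Wnt4 at -0.31 ± 0.11; 0 rose, 0 fell and 30 did not pass, adjusted over the list alone 0 rose and 1 fell, and the median was -0.10 (camera adjusted p = 0.0358; adjusted p = 0.740 with an estimated correlation). The 62 genes became 1 without knockout later 1, 8 without knockout later 2, 34 without control later 2, 104 without control first 5 and 114 without both control first 5 and knockout first 1, which shared 54 of the 62. List calls were lost for complement (adjusted p = 0.1996) without control later 1, and for cholesterol synthesis without control later 1 (0.634) or knockout later 1. Matrix remodelling lost its call without control later 1 (0.381), knockout later 2, control first 3 or control first 4, and BMP and Wnt signalling without knockout later 2 (0.124), either control array of the fourth pregnancy or control first 3. The mean of complement genes, -0.14, was -0.02 without control later 1 and -0.25 without control later 2, and that of matrix remodelling, -0.12, was -0.07 without control later 1 and -0.06 without knockout later 2. The cholesterol synthesis mean, -0.15, was -0.03 without control later 1, -0.06 without knockout later 1, -0.24 without knockout later 2 and -0.27 without control later 2.

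The knockout effects of the first and the fourth pregnancy went largely the same way. Of the 412 genes changed in the first pregnancy, 399 (96.8%) had the same sign in the fourth, against 61.0% of all genes. Of the 62 changed in the fourth, 60 had the same sign in the first. The genes that rose in both numbered 21, where 0.400 would be expected of independent sets. Those that fell in both numbered 23, where 0.588 would be expected, and 0 moved in opposite directions. Both comparisons use the same estimated spread of each gene, so the sets are not independent and the expected numbers may be too low. Across 13025 genes, which are not independent replicates, Pearson r of the log2 fold changes was 0.593 and Spearman rho 0.400. In the exact two-sided permutation test of the labels p was 0.0333, the smallest it can give, and the highest r in size among the other assignments was 0.486. Among genes changed in the first pregnancy, the slope of the fourth-pregnancy on the first-pregnancy effect was 0.715. Without knockout first 2 r was 0.542 and without control later 2 it was 0.425, and p was then 0.0667.

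**Figure D3:**
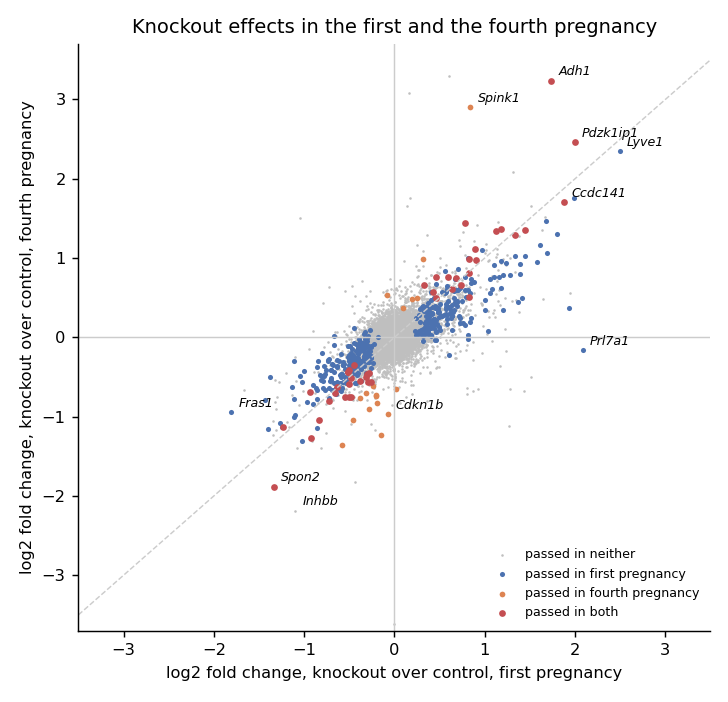
Log2 fold change of knockout over control in the first (x axis) and the fourth (y axis) pregnancy for 13025 genes, coloured by the comparison in which each gene passed. The dashed line marks equal effects. Genes that passed in both went the same way in both, 21 higher and 23 lower, and r across genes is 0.593.

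No single gene passed the test for a knockout effect that differed between pregnancies, with limma giving 0 genes, 650 at an unadjusted p under 0.05 and a lowest adjusted p of 0.505. Gene lists of immune genes and of trophoblast were shifted downward in this difference, and cell division lists upward, none of them with an estimated correlation. The gene with the lowest p was Cdkn1b, whose difference was -0.90 ± 0.13 and -0.03 by its second probe set. Prl7a1, at 49.7 ± 16.1 in first-pregnancy knockout decidua and 8.25 ± 1.15 in the fourth, had a difference of -2.25 ± 0.46 (adjusted p = 0.921). The others named by smallest p were Tmem35a (-0.63 ± 0.11), Necab2 (-0.58 ± 0.11), Fxyd5 (-0.66 ± 0.14), Zcchc17 (0.63 ± 0.10), Sh3gl3 (0.65 ± 0.12), Smarca1 (0.63 ± 0.14), the splicing kinase Clk4 (0.39 ± 0.09) and Cep131 (0.48 ± 0.11).

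Trophoblast markers had the largest median difference of the 8 lists, -0.50: 0 rose, 0 fell and 12 did not pass, and adjusted over the list alone 0 rose and 4 fell (camera adjusted p = 4.04e-07; adjusted p = 0.352 with an estimated correlation). Prl5a1 (-1.55 ± 0.48), Plac1 (-0.84 ± 0.28) and Prl4a1 (-1.92 ± 0.63) followed Prl7a1. In the fourth pregnancy Prl4a1 measured 24.1 in control later 1, 7.92 in control later 2, and 7.79 and 7.48 in the knockout arrays. Prl5a1 measured 19.5, 6.22, 5.62 and 5.73 in the same order. The fourth-pregnancy part of both differences thus rested on control later 1. Class I antigen presentation had a median difference of -0.33, with Tap1 at -0.44 ± 0.11; 0 rose, 0 fell and 12 did not pass, and adjusted over the list alone 0 rose and 3 fell (camera adjusted p = 2.06e-07; adjusted p = 0.448 with an estimated correlation). Interferon-stimulated genes had one of -0.31, with Oas2 at -0.46 ± 0.17 (camera adjusted p = 4.04e-07; adjusted p = 0.836 with an estimated correlation). Cholesterol synthesis had one of -0.28, with Srebf2, a regulator of that pathway, at -0.28 ± 0.12 (camera adjusted p = 7.61e-06; adjusted p = 0.836 with an estimated correlation). Natural killer cell markers had -0.28 (camera adjusted p = 0.0346; adjusted p = 0.836 with an estimated correlation). Endothelial markers had -0.14 (camera adjusted p = 0.00332; adjusted p = 0.836 with an estimated correlation). Mitosis, with Aurkb at 0.35 ± 0.17, had 0.20 (camera adjusted p = 0.00113; adjusted p = 0.836 with an estimated correlation). DNA replication had 0.17 (camera adjusted p = 0.0223; adjusted p = 0.836 with an estimated correlation). In these last 6 lists 0 members passed over all genes or adjusted over the list alone. The mitosis call was lost without knockout later 2 (adjusted p = 0.296), knockout first 1, control first 4 or control later 1. That of DNA replication was lost without control later 1 (0.644), knockout later 2, knockout first 1, control first 3 or control first 4, and the endothelial call without knockout later 2 (0.456), control first 3 or control later 2. The natural killer call was lost without knockout later 1 (0.791), control later 1, knockout first 1, knockout first 3, control first 3 or control first 5, and its mean of -0.24 ranged from -0.66 (without control later 2) to 0.18 (without control later 1). The mean of cholesterol synthesis, -0.27, was -0.15 without control later 1 and -0.16 without control first 4, and that of interferon-stimulated genes, -0.32, was -0.21 without control first 4. The mean of mitosis, 0.22, ranged from 0.11 (without knockout later 2) to 0.34 (without control first 5), that of DNA replication, 0.16, from 0.08 (without knockout later 2) to 0.27 (without control first 5), and that of endothelium, -0.18, from -0.29 (without control later 1) to -0.07 (without control later 2).

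The mean knockout effect of both pregnancies changed 691 genes, of which 343 rose, 348 fell and 51 changed over 2-fold; 2463 had an unadjusted p under 0.05, where 651 would be expected. Adh1 (2.49 ± 0.27), Lyve1 (2.42 ± 0.31) and Pdzk1ip1 (2.23 ± 0.19) rose most. Inhbb, an activin subunit, fell from 184 ± 103 to 76.5 ± 15.6 in the first (SD, n = 3 each) and from 300.4 ± 161 to 59.6 ± 19.96 in the fourth pregnancy (SD, n = 2 each), a mean of -1.64 ± 0.33, while a dimmer probe set gave -0.09. Ccdc141 had the smallest adjusted p, 2.15e-05, at 1.79 ± 0.08; its 3 other probe sets gave 1.76, 0.58 and 0.09.

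Vwce (1.87 ± 0.22), the neuropeptide receptor Qrfpr (1.70 ± 0.24), Fam210b (1.57 ± 0.18), Bco1 (1.55 ± 0.24), Cldn3 (1.4 ± 0.12) and Gpld1, which cleaves glycolipid membrane anchors (1.39 ± 0.14), made up the other large rises. Rbp4, the carrier of retinol in blood, fell from 299 ± 61.6 to 114 ± 6.16 in the first pregnancy and from 203 ± 127 to 86.3 ± 13.2 in the fourth (-1.20 ± 0.24). Chat, the enzyme that makes acetylcholine, fell from 21.5 ± 7.51 to 8.16 ± 0.880 and from 31.2 ± 8.35 to 10.2 ± 3.45 (-1.16 ± 0.17). Spon2 (-1.61 ± 0.16), Fras1 (-1.38 ± 0.22), Coch (-1.28 ± 0.18), Ak1 (-1.19 ± 0.13), C1qtnf2 (-1.18 ± 0.12), Enpp3 (-1.17 ± 0.16) and the immune receptor Cd200r4 (-1.13 ± 0.25) fell too. Other probe sets gave -0.07 for Spon2, -0.40 for Fras1, and 0.03, -0.78 and -1.57 for Enpp3.

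Decidual stromal markers moved both ways in the mean effect: of 26, 3 rose, 4 fell and 19 did not pass, and adjusted over the list alone 4 rose and 9 fell (camera adjusted p = 0.223). The decidual prolactin-family hormone Prl3c1 rose from 2658 ± 844 to 5554 ± 5.36 in the first and from 2367 ± 110.2 to 4466 ± 643 in the fourth pregnancy (1.01 ± 0.15). Lifr, a receptor subunit for leukaemia inhibitory factor (0.48 ± 0.07), and the peptide hormone Adm (0.90 ± 0.18) rose as well. Des, which encodes desmin (-0.37 ± 0.04), Alpl (-1.06 ± 0.14), Igfbp4 (-0.56 ± 0.09) and Wnt4 (-0.35 ± 0.07) fell. Decidual hormone Prl8a2 was at 0.09 ± 0.04 and did not pass.

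Natural killer cell markers were shifted upward in the mean effect, with a median of 0.58; 0 rose, 0 fell and 19 did not pass, and adjusted over the list alone 10 rose and 0 fell (camera adjusted p = 8.5e-07; adjusted p = 0.794 with an estimated correlation). Tyrobp (0.62 ± 0.16), Gzmf (1.14 ± 0.30), Gzmg (1.59 ± 0.42) and Gzma (1.09 ± 0.31) had the smallest p. Interferon-stimulated genes had a median of 0.14, and Ifit1 (0.89 ± 0.20) and Ifit3 (0.42 ± 0.10) rose, 0 fell and 26 did not pass. With these genes adjusted over the list alone, 2 rose and 0 fell (camera adjusted p = 0.00321; adjusted p = 0.794 with an estimated correlation). In the unfolded protein response, Asns (0.44 ± 0.10), which makes asparagine, and Herpud1 (0.57 ± 0.13) rose, 0 fell and 21 did not pass. For this list adjusted over the list alone, 3 rose and 0 fell, and the median was 0.08 (camera adjusted p = 0.000542; adjusted p = 0.794 with an estimated correlation). Of 20 epithelial markers Spink1 (1.87 ± 0.30), Cldn3 and Cdh1 (0.54 ± 0.08) rose, Epcam (-1.04 ± 0.15) fell and 16 did not pass. Adjusted over the list alone 6 rose and 1 fell, with a median of 0.08 (camera adjusted p = 0.0277; adjusted p = 0.794 with an estimated correlation).

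Complement and coagulation genes were shifted downward in the mean effect, with C1s1 (-0.61 ± 0.07), Cd59a (-0.54 ± 0.07), Serping1 (-0.43 ± 0.06) and C2 (-0.71 ± 0.13) among the 5 that fell; 0 rose and 15 did not pass. Adjusted over the list alone, 3 rose and 7 fell, and the median was -0.09 (camera adjusted p = 0.0309; adjusted p = 0.794 with an estimated correlation). In BMP and Wnt signalling Fzd7 (-0.62 ± 0.07), Sfrp5 (-0.62 ± 0.11), Wnt4 and the receptor Bmpr1a (-0.23 ± 0.05) fell, 0 rose and 26 did not pass. Adjusted over the list alone 2 rose and 6 fell of these, with a median of -0.09 (camera adjusted p = 0.00586; adjusted p = 0.794 with an estimated correlation). Among 19 collagens Col5a1 (-0.63 ± 0.09) fell, Col15a1 (0.42 ± 0.10) rose and 17 did not pass. For collagens adjusted over the list alone, 1 rose and 4 fell, with a median of -0.12 (camera adjusted p = 0.0492; adjusted p = 0.794 with an estimated correlation). Mitosis genes had a median of -0.16; 0 rose, 0 fell and 26 did not pass, and adjusted over the list alone 0 rose and 0 fell (camera adjusted p = 0.00141; adjusted p = 0.794 with an estimated correlation). The 691 genes became 1042 without control first 5, 438 without knockout first 3, 447 without control first 3, 252 without knockout later 1, 351 without knockout later 2 and 383 without control later 2. Calls were lost for interferon-stimulated genes without control first 4 (adjusted p = 0.0523), for epithelium without control first 5 (0.148), and for complement without control first 5 (0.165), knockout later 2 or control later 1. That for collagens was lost without control later 2 (0.144), knockout later 2, knockout first 1, control first 3 or control first 4. The mean of complement genes, -0.06, was -0.02 without control first 5 and -0.12 without control later 2, and its sign turned, to 0.0011, without control later 1. The mitosis mean, -0.16, was -0.10 without knockout later 1.

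The other 36 lists did not pass in the mean effect, the lowest camera adjusted p being 0.0881 for matrix remodelling, in which Eln (1.16 ± 0.26) rose and Sparc (-0.19 ± 0.04) fell. The chemokine Cxcl14 fell from 2429 ± 54.8 to 1275 ± 92.1 in the first and from 2392 ± 96.4 to 1486 ± 52.8 in the fourth pregnancy (-0.81 ± 0.05), the only 1 of 18 chemokines to pass. Ptgs2, which starts prostaglandin synthesis (0.81 ± 0.15), rose in the lists of 25 cytokines and inflammatory mediators, with Lcn2 (0.76 ± 0.13), and of 12 prostaglandin genes, with Slco2a1 (0.43 ± 0.09), while Pla2g4a (-0.35 ± 0.07) fell. Among 21 progesterone-responsive genes Il13ra2 (1.06 ± 0.23) and Fkbp5 (0.41 ± 0.08) rose, and Gata2 (-0.36 ± 0.05) and Wnt4 fell. Lcn2 alone rose among 19 oestrogen-responsive genes and 8 neutrophil markers. Among 27 angiogenesis genes Vegfc (0.42 ± 0.07) and Adm rose and Vegfd (-0.38 ± 0.08) fell. In the oxidative stress response Gsr (-0.61 ± 0.11) and Gpx1 (-0.40 ± 0.03) fell, among immediate early genes Ccn2 (0.70 ± 0.15) and Dusp1 (0.49 ± 0.09) rose, and among apoptosis genes Bik (0.59 ± 0.10) and Birc2 (0.31 ± 0.04) rose. Of 25 Notch pathway components Dtx2 (0.55 ± 0.13) and Mib1 (0.24 ± 0.05) rose and Neurl1a (-0.46 ± 0.09) fell.

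Lyve1 rose among endothelial markers, Ndufs4 (0.17 ± 0.04) in the respiratory chain, Dnajb4 (0.36 ± 0.07) among heat shock genes and Upk3b (0.31 ± 0.07) among markers of fat and mesothelium. Cdkn1b (-0.52 ± 0.06, and 0.04 by its second probe set) fell among cyclins and inhibitors of decidual polyploidy, Rps19 (-0.13 ± 0.03) among ribosomal proteins, Des among smooth muscle markers and Prl8a9 (-0.78 ± 0.16) among trophoblast markers. Of 14 markers of visceral endoderm and yolk sac Spink1 rose and Rbp4 fell. In the lists of Notch receptors and ligands, DNA replication, glycolysis and hypoxia, cholesterol synthesis, class I and class II antigen presentation, steroid metabolism and receptors, macrophages, T and B cells, dendritic cells, epiblast and mesoderm, primitive erythroid cells and adult red cells limma gave 0 members; adjusted over the list alone, 1 of steroid metabolism and 1 of dendritic cells rose.

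**Figure D4:**
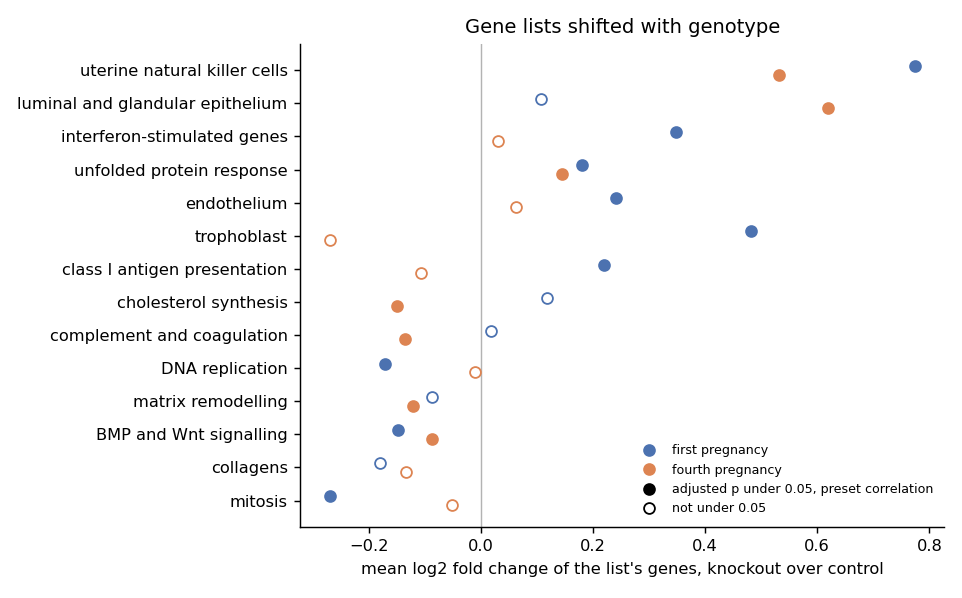
Mean log2 fold change of knockout over control (x axis) of the 14 gene lists that passed in the first pregnancy, the fourth pregnancy or the mean of both, for the first (blue, n = 3 per group) and the fourth (orange, n = 2 per group) pregnancy. Filled points had an adjusted p under 0.05 at the preset correlation and open points did not; with an estimated correlation 0 did. Natural killer cell markers lie at 0.77 and 0.53.

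Between the fourth and the first pregnancy of control mice, 2 genes changed. Prss35 rose from 32.9 ± 5.16 (SD, n = 3) to 92.7 ± 17.7 (SD, n = 2), a log2 fold change of 1.39 ± 0.15 (adjusted p = 0.0463), and Acsbg1 fell from 94.6 ± 13.9 to 48.0 ± 1.4 (-0.91 ± 0.10; adjusted p = 0.0463). At an unadjusted p under 0.05 limma gave 959 genes, where 651 would be expected. The genes of next smallest p did not pass: the arginase Arg2 (1.26 ± 0.16), Abca13 (0.78 ± 0.10), Tmem35a (0.59 ± 0.08), the glutathione peroxidase Gpx1 (0.31 ± 0.05), Epdr1 (-0.46 ± 0.07), Zcchc17 (-0.39 ± 0.07), the transcription factor Cebpd (-0.45 ± 0.09) and the splicing kinase Clk1 (-0.34 ± 0.07). Other probe sets gave -0.17 for Cebpd, and -0.58 and -0.19 for Epdr1. Prss35, Acsbg1, Abca13 and Tmem35a were also named in the fourth-pregnancy knockout effect, there with the opposite sign. Both comparisons use the same control arrays of the fourth pregnancy, so these results are not independent. A deviation of those arrays could give both. Acsbg1 was lower in the fourth pregnancy of knockout mice too, without passing.

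Several lists differed between the control pregnancies at camera's preset correlation, and 0 of 44 with an estimated one. In each of these lists 0 members passed over all genes. Natural killer cell markers were lower in the fourth, with a median of -0.47 and Gzma at -1.4 ± 0.43 (camera adjusted p = 6.44e-06; adjusted p = 0.756 with an estimated correlation). The unfolded protein response had a median of -0.06 (camera adjusted p = 0.00297; adjusted p = 0.756 with an estimated correlation). Higher in the fourth was cholesterol synthesis, with a median of 0.29 and Hmgcs1 at 0.42 ± 0.11 (camera adjusted p = 2.07e-05; adjusted p = 0.756 with an estimated correlation). So was the respiratory chain, with 0.08 and Sdhd at 0.19 ± 0.05 (camera adjusted p = 1.32e-05; adjusted p = 0.756 with an estimated correlation). Smooth muscle markers had a median of 0.24, with Cald1 at 0.46 ± 0.07, and adjusted over the list alone 4 rose and 0 fell (camera adjusted p = 0.00104; adjusted p = 0.756 with an estimated correlation). Mitosis genes had 0.18 (camera adjusted p = 0.00143; adjusted p = 0.935 with an estimated correlation) and collagens 0.26 (camera adjusted p = 0.00410; adjusted p = 0.756 with an estimated correlation). Glycolysis and hypoxia had 0.11 (camera adjusted p = 0.00491; adjusted p = 0.756 with an estimated correlation) and matrix remodelling 0.15 (camera adjusted p = 0.0443; adjusted p = 0.756 with an estimated correlation). Adjusted over the list alone, 0 members passed in the other 8 lists. The count of 2 genes was 5 without control later 2, 3 without control first 5, and 0 without any 1 of the 5 knockout arrays, control first 3 or control first 4. Calls were lost without control later 2 for natural killer cells (adjusted p = 0.482), collagens (0.0936), the unfolded protein response (0.0532) and mitosis, and for mitosis also without control first 5 (0.553). They were lost without control later 1 for cholesterol synthesis (0.0895), glycolysis (0.425) and matrix remodelling (0.668), and for the last also without knockout first 2, control first 3 or control first 5. The natural killer mean, -0.52, was -0.10 without control later 2, -0.33 without control first 4 and -0.94 without control later 1. Without control first 5 the mean went from 0.18 to 0.06 for mitosis, from 0.22 to 0.13 for collagens and from 0.24 to 0.16 for smooth muscle. The cholesterol mean, 0.25, was 0.13 without control later 1 and 0.14 without control first 4, the glycolysis mean, 0.08, was 0.05 without control later 1, and the mean of the unfolded protein response, -0.10, was -0.06 without control later 2.

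In knockout mice, 9 genes changed between the pregnancies, 7 higher and 2 lower in the fourth. The offset, filter, quantile and probe set settings also gave more higher genes. A fit on only the knockout arrays gave 14 higher and 20 lower, and one without control first 3 gave 0 higher and 4 lower. Arg2 rose from 6.43 ± 0.983 (SD, n = 3) to 21.5 ± 4.65 (SD, n = 2), a log2 fold change of 1.27 ± 0.16, beside 1.26 ± 0.16 in control mice. Cdkn1b fell from 139 ± 6.19 to 65.7 ± 3.87 (-1.04 ± 0.09), and -0.07 by its second probe set, and the iodide transporter Slc5a5 from 31.3 ± 2.90 to 9.53 ± 0.947 (-1.37 ± 0.18), and -0.18 by its second. Gpx1 rose from 2114 ± 50.2 to 2809 ± 82.8 (0.41 ± 0.05). Shisa4 (1.03 ± 0.13), the collagen Col8a1 (0.82 ± 0.11), Sh3gl3 (0.67 ± 0.08), the tropomyosin Tpm1 (0.66 ± 0.08) and the nuclear receptor Nr2f1 (0.61 ± 0.08) rose, with 0.38 by a second probe set of Col8a1 and 0.80 and 0.05 by others of Tpm1; Acsbg1 (-0.69 ± 0.10), Pam (-1.24 ± 0.18) and Ptpn22 (-0.45 ± 0.07) did not pass. At an unadjusted p under 0.05 there were 2284 genes, where 651 would be expected.

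Lists of cell type markers and pathway genes differed between the knockout pregnancies at camera's preset correlation, and 0 of 44 with an estimated one. In each of these lists 0 members passed over all genes. Natural killer cell markers were lower in the fourth, with a median of -0.82 and Il2rb at -0.94 ± 0.29 (camera adjusted p = 3.32e-09; adjusted p = 0.632 with an estimated correlation). Beside them, interferon-stimulated genes had -0.35, with Oasl2 at -0.84 ± 0.20 (camera adjusted p = 4.26e-09; adjusted p = 0.632 with an estimated correlation). Class I antigen presentation had -0.32, with Psmb9 at -0.50 ± 0.10 (camera adjusted p = 1.06e-05; adjusted p = 0.632 with an estimated correlation). Trophoblast markers had -0.21, with Prl7a1 at -2.08 ± 0.33 (camera adjusted p = 0.000146; adjusted p = 0.632 with an estimated correlation). Lower, too, was the unfolded protein response, with -0.13 (camera adjusted p = 0.000560; adjusted p = 0.632 with an estimated correlation) and endothelium -0.09 (camera adjusted p = 0.0267; adjusted p = 0.745 with an estimated correlation). Higher in the fourth were mitosis genes, with 0.40 and Aurkb at 0.44 ± 0.12 (camera adjusted p = 4.26e-09; adjusted p = 0.632 with an estimated correlation). DNA replication was higher too, with 0.31 and Mcm3 at 0.37 ± 0.10 (camera adjusted p = 6.95e-05; adjusted p = 0.673 with an estimated correlation). Epithelial markers had 0.40, with the keratin Krt18 at 1.16 ± 0.24 (camera adjusted p = 0.0176; adjusted p = 0.632 with an estimated correlation). Smooth muscle markers had 0.31, with Tagln at 1.20 ± 0.27 (camera adjusted p = 0.00170; adjusted p = 0.632 with an estimated correlation). The respiratory chain had 0.11 (camera adjusted p = 8.52e-05; adjusted p = 0.632 with an estimated correlation). Adjusted over the list alone, 16 mitosis, 7 smooth muscle and 6 epithelial genes rose, and 3 class I, 2 interferon-stimulated, 1 natural killer, 1 trophoblast and 1 epithelial gene fell. The 9 genes became 0 without knockout first 1, knockout first 3 or knockout later 1, 1 without knockout first 2 or knockout later 2, 4 without control first 3 or control first 4, 14 without either control array of the fourth pregnancy and 23 without control first 5. The epithelial call was lost without knockout later 1 (adjusted p = 0.106) and the endothelial one without knockout first 2 or knockout later 2 (highest 0.650). The endothelial mean, -0.11, was -0.01 without knockout later 2, -0.07 without knockout first 2 and -0.21 without knockout later 1. The natural killer mean, -0.76, was -0.49 without knockout later 1, and that of the unfolded protein response, -0.14, was -0.09 without knockout first 3.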

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

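The tests of natural killer, trophoblast and Notch1 explanations were chosen only after the results were seen, except the exchange of labels and the splits of the arrays, which were planned.

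The knockout effect differed between the pregnancies for 8 gene lists by the camera test of the difference itself, and each call was lost with an estimated correlation. The mean difference, the fourth minus the first pregnancy, was -0.33 for class I antigen presentation, -0.32 for interferon-stimulated genes and -0.75 for trophoblast markers. It was -0.27 for cholesterol synthesis, 0.22 for mitosis, -0.18 for endothelium, 0.16 for DNA replication and -0.24 for natural killer cell markers. With 1 array left out 6 of these 8 means moved over 1.5 times. Cholesterol synthesis was at -0.15 without control later 1 and -0.16 without control first 4, and interferon-stimulated genes were at -0.21 without control first 4. Mitosis was at 0.11 without knockout first 1 or knockout later 2, 0.13 without control first 4, 0.34 without control first 5 and 0.33 without knockout later 1. DNA replication was at 0.09 without knockout first 1, 0.08 without control first 4, control later 1 or knockout later 2, 0.27 without control first 5 and 0.24 without knockout later 1. Endothelium was at -0.07 without control later 2, -0.08 without control first 3 or knockout later 2, -0.28 without knockout later 1 and -0.29 without control later 1. The natural killer list was at -0.07 without control first 3, -0.43 without control first 4, -0.51 without knockout later 2 and -0.66 without control later 2, and turned to 0.03 without knockout later 1 and 0.18 without control later 1. Outside the genes tested, 4211 probe sets without exactly 1 gene symbol passed the filter, and 126 of them (2.99%, against 4.195% of probe sets with 1 symbol) were called in the mean knockout effect, 46 higher and 80 lower.

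As a list, markers of uterine natural killer cells were shifted upward in the mean knockout effect, with a median log2 fold change of 0.58, but 0 of 19 passed over all genes and the call was lost (adjusted p = 0.794 with an estimated correlation); Gzmd, the most abundant, was at 1152 ± 396 in control and 2449.9 ± 147 in knockout arrays of the first pregnancy, and Eomes is also in an embryo list. Fcer1g and Tyrobp, members of the list, are not particular to natural killer cells among leukocytes. More leukocytes of every kind could raise the list. The other 45 leukocyte markers had a median of 0.015 with an interquartile range of 0.182, which argues against that. Of the markers on the array, 21 of 23 for macrophages, 10 of 14 for dendritic cells, 8 of 15 for neutrophils and 6 of 18 for T and B cells were tested. Their signals were not compared with the offset, so a rise in dim markers may be missed. Against a single array as the cause of the mean effect, the lowest mean of the natural killer list without any 1 array was 0.44 (0.65 with all). In the fourth pregnancy, however, its mean of 0.53 was 0.11 without control later 2. There the median of knockout later 1 (-0.38) lay below that of control later 1 (-0.24), so a single array stays open in that pregnancy. The exact permutation p of the list mean was 0.0333, and the smallest possible is 0.0167; since this list was picked from 44, spread between mice unrelated to genotype cannot be told apart from a genotype effect. More of these cells or more transcript per cell, with Notch1 loss or with Cre at Pgr, stay open as untested biological explanations.

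The list of trophoblast markers was shifted upward in the first-pregnancy knockout effect, with a median of 0.26, but 2 of 12 passed and the call was lost (adjusted p = 0.677 with an estimated correlation); Prl8a9, their most abundant gene, was at 435 ± 94.8 in control and 312 ± 87.5 in knockout arrays. The lowest mean without any 1 array was 0.41, against 0.48 with all, which argues against a single array as the cause. Embryo tissue left after dissection, which per the labels removed it, might carry them: 25 markers of embryo lists had a median of 0.067 with an interquartile range of 0.206. Their median signal in control arrays was 9.28, close to the offset of 4.15, so this cannot be told apart. A difference in maternal or placental development stays open as untested.

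Notch1 signal was not lower in knockout decidua, with a mean log2 fold change of 0.12. Exchanged labels of 1 knockout and 1 control array might explain this, but each of 13 such exchanges gave at most 1 called gene, against 691 with the labels as deposited, which argues against it; an exchange of all labels was not tested. Both probe sets may lie outside the deleted part of the gene, and since the labels name no exons this cannot be told apart from incomplete deletion or Notch1 in cells without Cre.

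Of 60 splits of the arrays within each pregnancy, only the real one reached 691 genes in the mean knockout effect, against at most 1 in the others. That rank among 60 argues against a chance split but does not exclude it. Most other splits mix knockout and control arrays, which widens the error and lowers their counts. The 10 splits of the first-pregnancy arrays are too few for a share under 0.05; the real split gave 412 genes and the highest of the others gave 0.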

How the results depend on the processing

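Leaving out the arrays that stand apart on the first or second component (knockout first 1 and control first 5) was chosen after seeing the data. So was leaving out arrays for lists, and the other alternatives were planned. Over offset, scaling, filter, probe set and moderation settings, the first-pregnancy count of 412 ranged from 389 to 566, the fourth-pregnancy count of 62 from 46 to 84, and the count for the difference stayed at 0. Fitting only the arrays of the comparison gave 246 genes in the first pregnancy, 53 in the fourth, 0 between control pregnancies and 34 between knockout pregnancies; such fits hold fewer arrays. The mean effect ranged from 637 to 695 genes, and testing every probe set gave 1083, which counts some genes more than once. Between control pregnancies the count of 2 was 4 without a filter, and 0 with the stricter filter, with every probe set or with plain moderation; between knockout pregnancies plain moderation gave 2 in place of 9, and the cause was not tested. Without the arrays that stand apart there were 424 genes in the first pregnancy, 234 of them shared with the 412, 114 in the fourth, 54 of them shared with the 62, and 860 in the mean effect, 562 of them shared with the 691; the cause was not tested. With 1 array left out the counts ranged from 106 to 805 (the first pregnancy), 1 to 104 (the fourth), 0 to 3 (difference), 252 to 1042 (mean effect), 0 to 5 (control pregnancies) and 0 to 23 (knockout pregnancies), and the correlation of effects from 0.425 to 0.623. The correlation was 0.567 to 0.628 under the other settings. Of 52 list calls, 0 held with an estimated correlation, and 53 were made after quantile normalisation. An estimated correlation widens the error of lists whose genes vary together. Whether this alone removed the calls was not tested. The effect on Notch1 was 0.12 after quantile normalisation and 0.04 by its other probe set, and that on Pgr was 0.13 by another probe set and reversed, to -0.17, by the dimmest, the cause of which was not tested. Named genes were tried under both offset settings, quantile normalisation, plain moderation and the left-out fits of lowest and highest effect. Of 20, 15 passed in all of these in the first pregnancy, 3 in the fourth and 18 in the mean effect. Filter, probe set and comparison-only settings were not tried on them. In every fit with 1 array left out 6, 1 and 15 passed, and 0 changed sign. Some of these fits left a group with 1 array. The replicate numbers are not stated to pair the mice. With the number as a block, where 1 residual degree of freedom remains, 133 genes passed in the fourth pregnancy and 478 between knockout pregnancies, and 1737 and 3036 had an unadjusted p under 0.05; deviations of same-numbered arrays correlated at 0.18, 0.30, 0.22 and 0.095, against 0.50 for knockout first 1 with control first 5, which share no number. Signals near the offset of 4.15 limit fold changes of dim genes.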

Other observations

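The 7 gene families below and the test of genes beside Pgr were chosen only after the results were seen. Each family holds genes already called in this same mean effect, and its camera p was adjusted over the 7 alone. These family p describe the values and cannot count as evidence of a shift.

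Of 9 tested laminin chains, parts of basement membranes, 4 fell in the mean of both pregnancies, 0 rose and 5 did not pass, with a median of -0.10. Those that fell were Lamb2 (-0.76 ± 0.06), Lama1 (-0.84 ± 0.18), Lama2 (-0.65 ± 0.08) and Lama5 (-0.51 ± 0.07). Lamc1 (0.03), Lamb1 (-0.09), Lama4 (-0.10), Lama3 (-0.09) and Lamc3 (-0.02) did not pass. Lamb2 went from 732 ± 55.5 to 441 ± 41.6 in the first and from 849 ± 39.0 to 486 ± 19.0 in the fourth pregnancy, and the family's camera adjusted p was 0.000208 (adjusted p = 0.0899 with an estimated correlation). Of 19 cytosolic tRNA synthetases, which charge tRNA with amino acids, 5 rose, 0 fell and 14 did not pass, with Nars at 0.56 ± 0.11 and Cars at 0.37 ± 0.09 (camera adjusted p = 6.9e-05; adjusted p = 0.155 with an estimated correlation). Of 8 claudins Cldn3 and Cldn12 (0.25 ± 0.06) rose, 0 fell and 6 did not pass (camera adjusted p = 0.00194; adjusted p = 0.0899 with an estimated correlation). Quantile normalisation left these counts and the sign of each median as they were.

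The other 4 families had a camera adjusted p above 0.05, with the same limit. Desmosomal genes Dsc2 (0.93 ± 0.21) and Dsg2 (0.62 ± 0.14) rose among 8 (camera adjusted p = 0.250), and the Wnt receptors Fzd2 (-0.67 ± 0.12) and Fzd7 (-0.62 ± 0.07) fell among 10 frizzled genes (0.0978). Of 15 genes of retinoid handling Adh1 and Bco1 rose and Rbp4 fell (0.661). Of 8 prolactin-family genes Prl3c1 rose and Prl8a9 fell (0.265), and after quantile normalisation 2 rose and 1 fell. Chat (-1.16 ± 0.17) and Slc18a3, the vesicular transporter of acetylcholine (-0.41 ± 0.05), genes of a shared locus, both fell.

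The gland protease genes Prss28 and Prss29 had their highest signals in the knockout arrays of the fourth pregnancy. Prss28 measured 161.6 in knockout later 1 and 35.6 in knockout later 2, and at most 10.5 in the other arrays. Prss29 measured 382 and 83.8 in those arrays, and 5.63 to 57.2 in the others. Prl7a1 measured 33.6, 65.8 and 49.8 in the knockout arrays of the first pregnancy and 4.75 to 13.5 elsewhere. Afp stayed between 5.05 and 6.90 and Hbb-y between 3.89 and 5.70 in every array, near the offset.

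Flanking DNA carried with Cre at the Pgr gene may change genes beside Pgr, as a hypothesis for part of the mean knockout effect. Of 120 tested genes beside Pgr, 20 on one side and 100 on the other, 7 were called. That share was 5.83%, close to 5.31% of all genes (Fisher's exact test, two-sided p = 0.684). The count cannot decide about the whole effect, since 120 genes could never hold most of the 691 called. Changes that flanking DNA might cause in genes elsewhere were not tested. Other windows, of at most 20, 50 and 200 genes a side, held 2 of 40, 4 of 70 and 8 of 220 called genes (exact p = 1, 0.788 and 0.360). Effects of Cre or of the lost Pgr copy elsewhere in the genome were not separable from Notch1 loss in this design.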
